A study of Mus musculus with 6 samples.

How the data were processed

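RNA was measured in heart ventricle of 1-day-old (P1) C57BL6 mice by stranded sequencing of polyadenylated RNA. Of the 6 libraries, 3 came from wild-type (WT) mice and 3 from mice with a knockout (KO) of Rbpms, the gene of an RNA-binding protein with a single RNA recognition motif. Per the labels, the libraries of a group are biological replicates numbered 1 to 3. Nothing in the labels says how many animals went into each, so the p-values measure the spread between these libraries. Groups were taken from the sample titles.

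Gene expression values were RPKM (reads per kilobase of gene length and per 1000000 reads), as deposited by the authors for 14004 genes. A check on the deposited table found that RPKM multiplied by the listed gene length summed to 1000000 in each library, so the values were scaled to the total of the listed genes. Of the low values, 18.9 to 25.8% in 5 libraries and 50% in Rbpms KO replicate 1 lay within 0.1 of a whole multiple of a step. Reads per library were therefore not recovered, and the depth is unknown. The gene length in kilobases was given in the same deposited table. FastQC 0.11.4, featureCounts 1.6.0 and edgeR 3.30.1, with the builds GRCm38 and mm10, are named per the submitters' processing notes. The settings of these tools and the aligner are not given in the sources used here. In the authors' deposited comparison of the genotypes, fold changes and mean abundances were log2 values, per the file headers. The same deposited table gave a likelihood ratio score, a p-value and a false discovery rate (FDR) per gene, per the file headers. Its fold changes were KO over WT, because the deposited sheet of genes higher in WT holds negative values. In 20 cells of the RPKM table a spreadsheet had put a date in place of a gene symbol, and 18 were renamed through the gene ID of the authors' table. Of the 14004 genes, 13995 had an ID in GENCODE mouse release 21, from which gene positions were taken.

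The authors' deposited splicing tables are named after rMATS and cover 5 event types, namely skipped exons, mutually exclusive exons, alternative 3' and 5' splice sites and retained introns. Their inclusion levels are ratios of length-corrected junction read counts for each of 3 libraries in 2 sets, per the file headers. The headers do not say which set holds which genotype, and the sets are called the first and the second set throughout. No genotype was assigned to a set, and the library order within a set is not named. The version of rMATS and the annotation used are not given in the sources used here. In many cells the commas between the 3 read counts had been lost. The counts were recovered by cutting the digits so that both cells of a set gave the printed inclusion levels within 0.00051. Of the 56560 cell pairs for skipped exons, 4716 allowed more than 1 reading, and the one with the most even read totals was kept. On simulated data, 100% of 2000 pairs were read back exactly, but each of the 2000 allowed 1 reading, so the choice among several readings was not tested. Of 24658 exons in the skipped exon table, 24645 had the same ends as an exon of GENCODE release 21 on GRCm38.

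Genes with at least 0.5 RPKM in at least 3 of the 6 libraries were tested, which kept 12911 genes. Log2(RPKM + 0.5) was compared between genotypes with limma 3.58.1 in R 4.3.3, with a mean-variance trend and Benjamini-Hochberg adjustment over the genes tested, and genes with an adjusted p below 0.05 were called. Because no counts per library were used, no test built for counts was run. On simulated data for this comparison with 12911 genes and 200 changed genes in each of 20 simulations, 61.7% of the 1.5-fold and 95.6% of the 2-fold changes were recovered, and 5.98% of calls were false. The libraries were simulated as independent, so these rates do not cover libraries that share tissue. Rbpms and Rbpms2 were also compared with a two-sided exact permutation test, whose smallest possible p for 3 against 3 is 0.1.

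A total of 38 gene lists was fixed before the data were examined. They covered pathways of the heart muscle cell, the cell cycle, metabolism and stress, cell types of the heart, cell types from outside it, sex genes, neighbours of Rbpms and genes known for alternative exons in heart. The pathway and cell type lists with at least 5 tested members were compared with limma's camera at a preset correlation of 0.01, adjusted over 31 lists. On simulated data, camera called the raised list in 20 of 20 simulations and 0 of 600 unchanged lists. The simulated genes varied independently of each other, so false calls from correlated genes of a list were not tested. The fits with a correlation estimated from the data and limma's fry were alternatives. Fry asks whether the genes of a list move one way on balance and does not compare them with other genes. Another 8 lists were written after the values had been seen, and are named as such.

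Genes named in the text were Rbpms and Rbpms2, the 12 largest rises and 12 largest falls in log2 change among called genes whose groups did not overlap and whose higher group averaged at least 1 RPKM, leaving out predicted genes and pseudogenes, and up to 4 members per list with the smallest p. Of splicing events, the 10 skipped exons with the largest difference in inclusion and non-overlapping sets, 1 per gene and ties by the lower FDR, the largest event of each gene in the list of genes with alternative exons, and the 2 largest of each other event type were named. Results for a few genes that met these rules are not reported here. An event was counted at the authors' FDR below 0.05, a difference of at least 10 percentage points and a mean of at least 20 informative reads per library. A limma test of inclusion levels between the genotypes had been planned and was not run, because the sets carry no genotype, so the rule for named exons used the authors' threshold instead. Fisher's exact tests (two-sided) used scipy 1.17.1 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.

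The alternatives were leaving out each library in turn, the replicate number as a block, pseudocounts of 0.1 and 1, no filter or a mean of at least 1 RPKM, rescaling by the median ratio, other variance models, stricter thresholds, the authors' own comparison, and for splicing other thresholds, coverage minimums and reads. Chosen after seeing the data were the mean of WT replicates 1 and 2 as 1 sample, leaving out WT replicates 1 and 2 with Rbpms KO replicate 1, leaving out genes of airway, lung and squamous epithelium lists, and rescaling for the list tests. A sex covariate was not fitted, since sex is not among the labels and samples would have been grouped by measured values.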

Results

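Stranded RNA sequencing compared heart ventricles of 3 WT and 3 Rbpms KO libraries from mice on the first day after birth. The title of the series places the question in noncompaction cardiomyopathy, a disorder of the ventricular wall, and in the division of heart muscle cells, whose failure to complete cytokinesis leaves cells with a pair of nuclei. Expression was deposited as RPKM, and 12911 genes were tested and 1093 were not, together with the authors' own tables of expression changes and of splicing. The depth of the libraries is unknown. The first principal component of the log2 values held 53.3% of the variance and separated the genotypes, and the second held 24.3%. Correlations of log2 values across genes, which are not independent replicates, were 0.980 to 0.996 within groups and 0.964 to 0.980 between them. WT replicates 1 and 2 lay closer together than any other pair, with an SD of their log2 ratio of 0.132 over 3677 genes with a mean of at least 10 RPKM, against 0.244 to 0.496 for the other pairs. The labels do not say whether these 2 come from separate tissue, so they may not be independent, and each WT SD and p-value treats them as separate.

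Transcript of the targeted gene was nearly absent from the knockout libraries. Rbpms (ENSMUSG00000031586, GRCm38 chromosome 8, 33782643 to 33929863) measured 33.1, 35.7 and 38.1 RPKM in the WT libraries and 0.594, 0.276 and 0.240 RPKM in the Rbpms KO libraries. The means were 35.6 ± 2.50 RPKM (SD, n = 3) and 0.370 ± 0.195 RPKM (SD, n = 3), a log2 change of -5.40 (limma adjusted p = 5.31e-06; two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). Rbpms2, the paralog of Rbpms, also fell, from 37.5 to 20.9 RPKM (log2 change -0.84, limma adjusted p = 0.0127; exact permutation p = 0.1). The Rbpms2 call was lost without WT replicate 1 or WT replicate 2, where the adjusted p rose to at most 0.0645.

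Loss of Rbpms went with a lower level of 515 genes and a higher level of 307, or 822 of 12911 genes tested. Most changes were moderate, since 145 of the falls and 33 of the rises reached 2-fold. The deepest falls were in secretory genes of the airway lining, genes of contractile smooth muscle fell less, and the rises took in genes of cardiac stress, of interferon response and of the endocardium. Whether the airway and smooth muscle falls arose in cells of the ventricle or from airway tissue in the WT libraries was not settled. All 822 called genes had groups that did not overlap, as had 29.8% of all tested genes. Chance gives 10% if the 6 libraries are independent, which is not known for WT replicates 1 and 2. At an unadjusted p below 0.05 there were 3030 genes. The count depended on which libraries were kept, and most on WT replicates 1 and 2. It was 237 without WT replicate 1, 192 without WT replicate 2, 435 without Rbpms KO replicate 2, 525 without Rbpms KO replicate 3, and 211 (48 higher, 163 lower) when the mean of WT replicates 1 and 2 counted as 1 sample, an alternative chosen after seeing the data. It was 868 without WT replicate 3 and 795 without Rbpms KO replicate 1. In all 6 fits that left out 1 library 186 genes were called. No called gene changed sign, but groups that do not overlap cannot change sign when a library is left out. The authors' deposited table held 1553 genes at FDR below 0.05, 763 higher and 790 lower in KO, and 774 of the 822 genes were among them. Rescaling each library by its median ratio gave 426 higher and 414 lower genes, so the excess of falls depended on the scaling.

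Many of the steepest losses were of genes known from secretory cells of the airway, although Chad is a cartilage gene. This grouping was made after the values were seen. Airway tissue in the WT libraries could not be told apart from a fall within the ventricle. Scgb3a2, a secretoglobin, averaged 545 ± 96.1 RPKM in WT and 5.19 ± 7.96 RPKM in Rbpms KO (SD, n = 3 each). Scgb3a1 fell from 129 to 0.954 RPKM, Scgb1a1 from 50.2 to 1.01 RPKM and Reg3g, an antibacterial lectin, from 57.6 to 0.259 RPKM. Cbr2, Sec14l3, Wfdc2, AU040972, Cyp2f2, Agr2 and Chad completed the 12 largest falls with Rbpms, with log2 changes between -4.98 for Cbr2 and -3.80 for Chad. Limma's adjusted p ran from 1.24e-05 for Sec14l3 to 0.0274 for Cyp2f2 among these genes. Of the lung list fixed beforehand 4 of 9 genes were tested, and 3 fell over all genes and 3 when adjusted over the list alone, namely Scgb1a1, Sftpd (from 1.81 to 0.0355 RPKM) and Sftpb (from 2.01 to 0.0817 RPKM). Ager measured 0.857 and 1.11 RPKM and was not called. Each of these calls held without any 1 library, apart from Cyp2f2, whose adjusted p reached 0.115 without WT replicate 2 and which was also lost without WT replicates 1 or 3 or Rbpms KO replicates 2 or 3.

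Several markers of contractile smooth muscle fell. Acta2, smooth muscle actin, averaged 875 ± 78.7 RPKM in WT and 197 ± 42.6 RPKM in Rbpms KO (SD, n = 3 each). Cnn1, calponin, fell from 17.4 to 3.43 RPKM, Myh11, smooth muscle myosin, from 10.7 to 1.68 RPKM, and Synpo2 from 10.9 to 6.15 RPKM. Of 11 tested members of the list 6 fell and 0 rose over all genes, and 8 fell when adjusted over the list alone. The median log2 change was -0.79 (camera adjusted p = 1.10e-06, and adjusted p = 0.479 with an estimated correlation). Fry gave an adjusted p of 0.0171, its lowest of the 31 lists and the only one below 0.05. Airway genes fell in the same libraries, and smooth muscle of the airway as the source was left open. The calls of Acta2, Cnn1 and Myh11 held without each library in turn, and that of Synpo2 was lost without WT replicates 1 or 2 (adjusted p up to 0.0863). Among pericyte genes 0 of 8 changed, and the list was not called (median log2 change 0.11, adjusted p = 0.246), although Kcnj8 was called without Rbpms KO replicate 1 (adjusted p = 0.0279).

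**Figure D1:**
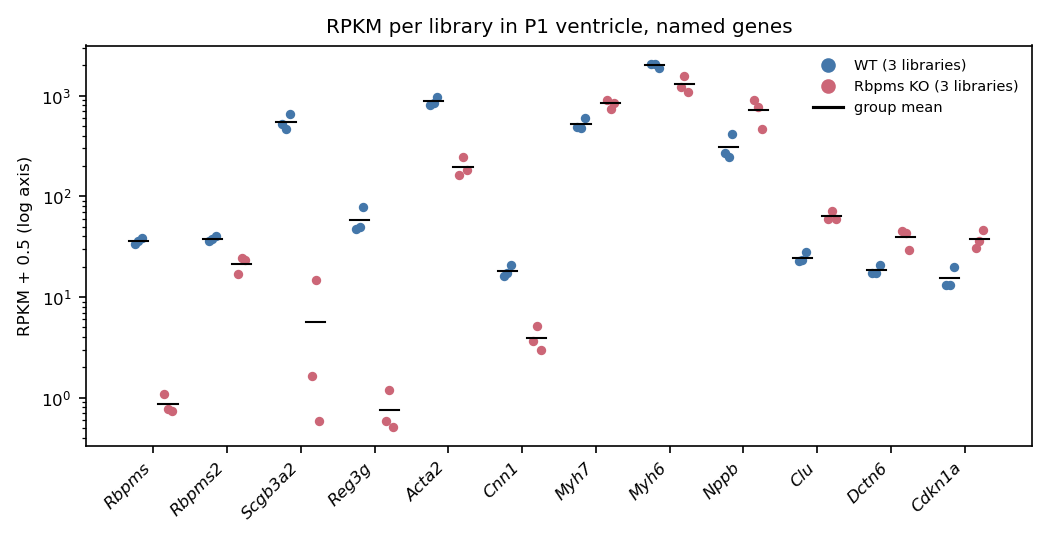
RPKM + 0.5 (log axis) of 12 named genes in each of the 3 WT and 3 Rbpms KO libraries of P1 ventricle, with a bar at the group mean. Rbpms averaged 35.6 RPKM in WT and 0.370 RPKM in Rbpms KO, and the groups did not overlap for any gene shown.

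The largest rises brought together genes of several functions. Dusp4, a phosphatase of MAP kinases, rose from 2.46 to 10.3 RPKM (log2 change 1.83, limma adjusted p = 0.00112). Clu, a secreted chaperone, rose from 24.1 to 63.3 RPKM, and Angpt1, a ligand of the endothelial receptor Tie2, from 14.4 to 38.2 RPKM. Xirp2, a protein of the intercalated disc, rose from 3.87 to 10.8 RPKM. Slc10a6, Fam107a, Trim54, Zbtb16, Cdkn1a, Fkbp5, Tigd4 and Lrrc2 made up the rest of the 12, with log2 changes from 1.82 for Slc10a6 to 1.28 for Lrrc2. The calls of Dusp4, Clu, Angpt1 and Xirp2 held without each library in turn. The other 8 calls were lost without WT replicate 1 or 2, except that Cdkn1a was lost without WT replicate 2 alone (adjusted p = 0.0519), and the highest adjusted p was 0.126 for Fam107a. Fam107a was also lost without Rbpms KO replicate 3, Trim54 without Rbpms KO replicate 2 and Lrrc2 without WT replicate 3.

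Within heart muscle genes, the myosin heavy chains moved in opposite directions. Myh7, the isoform that predominates before birth in the mouse ventricle, rose (518 ± 65.5 RPKM in WT and 836 ± 83.8 RPKM in Rbpms KO; SD, n = 3), and Myh6, the adult isoform, fell (2018 ± 103 RPKM in WT and 1295 ± 251 RPKM in Rbpms KO; SD, n = 3). Csrp3 rose from 184 to 287 RPKM and Myom2 from 48.5 to 87.9 RPKM. The sarcomere list had 3 rises and 1 fall among 26 genes (6 and 1 when adjusted over the list alone) and was not called, with a median log2 change of 0.03 and a camera adjusted p of 0.0679, although it was called without WT replicate 1 or Rbpms KO replicate 1 (adjusted p down to 0.00393). These 4 gene calls depended on single libraries. They were lost without WT replicates 1 or 2, Csrp3 also without each Rbpms KO library, Myom2 without WT replicate 3, and Myh6 without WT replicate 3 or Rbpms KO replicates 1 or 3, with adjusted p up to 0.150. The fall of Myh6 also lost its call after rescaling by the median ratio (adjusted p = 0.0547).

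The list of genes of the trabecular layer, the inner meshwork of the ventricular wall, was called higher at the preset correlation. Nppb, a natriuretic peptide, rose from 308 to 713 RPKM, Rasl11b from 16.3 to 30.9 RPKM and Irx5, a transcription factor, from 3.48 to 6.16 RPKM. Of 13 tested genes 3 rose (4 when adjusted over the list alone), with a median log2 change of 0.36 (camera adjusted p = 0.00515, and adjusted p = 0.518 with an estimated correlation). Slit2 measured 1.71 and 2.71 RPKM and was not called, except without Rbpms KO replicate 1 (adjusted p = 0.0155). In the compact layer list 0 of 11 genes changed (median log2 change -0.20, adjusted p = 0.0919; 0.0387 without WT replicate 1), and Prdm16, Ccnd1, Mycn and Fzd1 had log2 changes from -0.51 to -0.27 with adjusted p of 0.0865 or more, and Fzd1 was called without Rbpms KO replicate 1 (0.0362). Genes of notch and neuregulin signalling showed 1 rise among 17, that of Erbb4 (from 4.13 to 5.66 RPKM, adjusted p = 0.0499), and 0 when adjusted over the list alone (adjusted p of the list 0.199; 0.0499 without WT replicate 3). Erbb3, Notch1 and Nrg1 were not called, with log2 changes of -0.62, 0.44 and 0.63, but Erbb3 was called without Rbpms KO replicate 1 (0.0480) and Notch1 and Nrg1 without WT replicate 3 (0.0384 and 0.0413). The calls of Nppb, Rasl11b, Irx5 and Erbb4 were lost without WT replicates 1 or 2 and without Rbpms KO replicate 2. Nppb and Erbb4 were also lost without Rbpms KO replicate 1, and Irx5 and Erbb4 without Rbpms KO replicate 3 (adjusted p up to 0.217 for Erbb4).

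A few cell cycle genes fell, and 3 lists were called lower at the preset correlation, with small medians. In the G2 and mitosis list, Bub1b, of the spindle checkpoint, fell from 14.7 to 10.2 RPKM, Ccna2 from 36.6 to 25.7 RPKM and Ccnb2 from 30.4 to 23.2 RPKM, so that 3 of 20 genes fell (3 when adjusted over the list alone). That list's median log2 change was -0.18 (camera adjusted p = 0.00383, and adjusted p = 0.651 with an estimated correlation). Of 22 cytokinesis genes 1 fell, Kif20a, a kinesin of the spindle midzone (14.6 ± 0.251 RPKM in WT and 11.5 ± 0.463 RPKM in Rbpms KO; SD, n = 3), and it was also the 1 fall adjusted over the list alone. The median was -0.16 (camera adjusted p = 0.0346, and adjusted p = 0.731 with an estimated correlation). Prc1, Anln and Hmmr were not called, with log2 changes of -0.41, -0.29 and -0.34, and neither was Myh9 at 0.36, except without WT replicate 3 (adjusted p = 0.0297). In the list of G1, S phase and replication genes, 0 of 20 were called over all genes or over the list alone. It had a median of -0.23 (camera adjusted p = 0.0346, and adjusted p = 0.731 with an estimated correlation), and Mcm4, Cdc45, Cdt1 and Rrm1 had log2 changes from -0.45 to -0.27. Without Rbpms KO replicate 1 the 3 list calls were lost, with adjusted p of 0.106, 0.504 and 0.938 in this order. Without WT replicate 3 the cytokinesis and G1 lists were lost as well. The gene calls of Bub1b, Ccna2, Ccnb2 and Kif20a were lost without WT replicates 1 or 2, and all but Bub1b also without Rbpms KO replicate 3, Ccnb2 and Kif20a without Rbpms KO replicate 2, and Ccna2 without WT replicate 3 (adjusted p up to 0.179). After rescaling by the median ratio those of Ccna2, Ccnb2 and Kif20a were lost (adjusted p = 0.0808, 0.0660 and 0.0595).

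Some genes of stress and interferon response rose, while most members of these lists did not pass over all genes. In the p53 target list Cdkn1a, an inhibitor of the cell cycle, rose (14.9 ± 3.93 RPKM in WT and 37.3 ± 7.78 RPKM in Rbpms KO; SD, n = 3), Eda2r rose from 0.840 to 2.17 RPKM and Trp53inp1 from 9.41 to 20.5 RPKM. These were 3 of 16 tested genes over all genes and over the list alone (median log2 change 0.10, camera adjusted p = 0.00576, and adjusted p = 0.518 with an estimated correlation), and Perp measured 166 and 202 RPKM and was not called. Of 14 cardiac stress genes, Xirp2, Mybpc2 (from 1.73 to 4.56 RPKM) and Nppb rose, and over the list alone 7 rose and 1 fell. This list had a median of 0.47 (camera adjusted p = 0.00264, and adjusted p = 0.618 with an estimated correlation). Acta1 went the other way without passing the test over all genes (27.6 ± 6.67 RPKM in WT and 10.7 ± 6.23 RPKM in Rbpms KO; SD, n = 3). Interferon-response genes included Ifit3 (log2 change 1.20), Ifit1 (from 1.71 to 3.56 RPKM), Rtp4 (from 3.37 to 6.16 RPKM) and Xaf1 (from 1.69 to 3.14 RPKM) among 5 rises of 14 (11 when adjusted over the list alone). Their median was 0.56 (camera adjusted p = 5.59e-09, and adjusted p = 0.518 with an estimated correlation). Without WT replicate 2 the calls of Cdkn1a, Trp53inp1, Mybpc2, Ifit1 and Rtp4 were lost (adjusted p up to 0.143), Trp53inp1, Mybpc2 and Rtp4 also without WT replicate 1, Mybpc2 and Ifit1 without Rbpms KO replicate 2, and Trp53inp1 without Rbpms KO replicate 3. That of Nppb was lost without WT replicates 1 or 2 or Rbpms KO replicates 1 or 2 (up to 0.165). Those of Eda2r, Xirp2, Ifit3 and Xaf1 held without each library.

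In the immediate early list 0 of 12 genes passed over all genes and 4 rose when adjusted over the list alone. Its median log2 change was 0.35 (camera adjusted p = 6.64e-04, and adjusted p = 0.618 with an estimated correlation), and Klf2, Dusp1, Junb and Btg2 had log2 changes of 0.38, 0.48, 0.55 and 0.53. Dusp1 and Btg2 were called without Rbpms KO replicate 3 (adjusted p = 0.0481 and 0.0229), and Junb without WT replicate 3 (0.0496). After rescaling by the median ratio Klf2, Dusp1 and Junb were called (adjusted p = 0.0465, 0.0367 and 0.0463). In the list of the integrated stress response 1 of 14 genes rose, Ddit4 (from 8.64 to 19.1 RPKM), as it did over the list alone, and the list was not called (median -0.08 with camera upward, adjusted p = 0.660). Nupr1, Trib3 and Vldlr had log2 changes of -0.93, 0.31 and 0.31 and were not called. The call of Ddit4 was lost without WT replicates 1 or 2 (adjusted p up to 0.0900).

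Lists of fatty acid oxidation and oxidative phosphorylation were called lower at the preset correlation, while few of their genes passed the test. Of 19 genes of fatty acid oxidation, Cpt2 (from 20.7 to 13.8 RPKM), Acsl1 (from 57.4 to 42.4 RPKM) and Acaa2 (from 216 to 167 RPKM) fell, the same 3 in number over the list alone. The median log2 change was -0.19 (camera adjusted p = 0.0248, and adjusted p = 0.731 with an estimated correlation). Ppara had a log2 change of 0.30 and was not called. Oxidative phosphorylation had 0 of 20 genes called over all genes or the list alone, with a median of -0.13 (camera adjusted p = 0.0375, and adjusted p = 0.731 with an estimated correlation; adjusted p = 0.142 after rescaling by the median ratio). Uqcrc1 and Cyc1 had log2 changes of -0.24 and -0.30, and Cox6a2 and Cox8b of 0.31 and 0.29, none of them called, though Cox6a2 was without Rbpms KO replicate 1 (adjusted p = 0.0386). Of 19 glycolysis and hypoxia genes, Car9, a carbonic anhydrase induced by low oxygen, fell from 1.26 to 0.271 RPKM, Eno1 from 39.0 to 29.1 RPKM and Hk2 from 12.8 to 9.17 RPKM (4 falls over the list alone), and Hk1 had a log2 change of -0.61 without a call over all genes, except without Rbpms KO replicates 1 or 2 (adjusted p down to 0.0312). That list was not called (median -0.17, adjusted p = 0.0726), but was without WT replicates 1 or 2 or Rbpms KO replicate 3 (adjusted p down to 0.0222). The fatty acid list was lost without WT replicates 1 or 2 or Rbpms KO replicate 2 (adjusted p up to 0.161), and the oxidative phosphorylation list without WT replicate 1 or Rbpms KO replicates 1 or 2 (up to 0.250). Of the gene calls named here that of Car9 held without each library. Cpt2, Acsl1, Acaa2 and Hk2 were lost without WT replicates 1 or 2, Eno1 without WT replicates 2 or 3, all 5 without Rbpms KO replicate 3, all but Hk2 without Rbpms KO replicate 2, Acsl1, Eno1 and Hk2 without Rbpms KO replicate 1, and Hk2 without WT replicate 3, with adjusted p up to 0.209. After rescaling by the median ratio the calls of Acsl1, Acaa2, Eno1 and Hk2 were lost (adjusted p = 0.0907, 0.0760, 0.0594 and 0.0616).

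Calcium handling and ion channel genes moved both ways. Casq1 fell from 30.3 to 11.6 RPKM and Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell (1062 ± 110.2 RPKM in WT and 749 ± 84.9 RPKM in Rbpms KO; SD, n = 3), while Cacna2d1 and Hrc rose, with log2 changes of 0.37 and 0.32. Among 16 calcium genes 2 rose and 2 fell (2 and 3 over the list alone), and the list was not called (median 0.05, adjusted p = 0.614). Kcnd2 fell from 1.30 to 0.439 RPKM and Kcnj5 from 25.9 to 16.7 RPKM, while Scn10a and Kcne1 rose, with log2 changes of 0.55 and 0.40. Of 15 channel genes 2 rose and 2 fell (3 and 5 over the list alone), and the list was not called (median -0.17, adjusted p = 0.471). Among 21 splicing regulators Srsf1 fell from 53.5 to 39.1 RPKM and Celf1 from 31.3 to 24.5 RPKM (3 falls over the list alone; median 0.03, list adjusted p = 0.967). Rbfox1 and Mbnl1 had log2 changes of -0.58 and 0.31 and were not called, except Rbfox1 without WT replicate 3 (adjusted p = 0.0364). None of these 10 calls held without each library in turn. All were lost without WT replicate 2, with adjusted p from 0.0502 for Kcnd2 to 0.201 for Hrc, all but Kcnd2 without WT replicate 1, and Casq1, Cacna2d1, Hrc, Scn10a, Kcne1 and Celf1 without WT replicate 3. Without Rbpms KO replicate 1 Atp2a2, Scn10a and Kcne1 were lost, without Rbpms KO replicate 2 all but Kcnd2 and Kcnj5, and without Rbpms KO replicate 3 Cacna2d1, Atp2a2, Hrc, Scn10a, Kcne1 and Celf1. After rescaling by the median ratio Cacna2d1, Atp2a2, Hrc and Celf1 were lost (adjusted p = 0.0503, 0.0927, 0.0660 and 0.0863).

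Among cell types of the heart, some endocardial genes rose, with Npr3, a natriuretic peptide receptor, from 17.2 to 32.7 RPKM and Adgrg6 from 3.00 to 5.80 RPKM. With Tmem108 and Cgnl1, 4 of 8 rose (5 over the list alone), with a median log2 change of 0.47 (camera adjusted p = 1.85e-04, and adjusted p = 0.518 with an estimated correlation). In the endothelial list Emcn (from 13.9 to 25.6 RPKM), Pecam1 (from 41.4 to 59.6 RPKM) and Tie1 rose and Aplnr fell from 16.4 to 11.8 RPKM, or 3 rises and 1 fall of 13 (7 and 1 over the list alone; median 0.30, camera adjusted p = 0.00103, and adjusted p = 0.518 with an estimated correlation). Of 12 fibroblast genes Tcf21 (from 5.60 to 8.38 RPKM) and Postn (from 178 to 248 RPKM) rose, 2 over the list alone (median 0.12, camera adjusted p = 0.0375, and adjusted p = 0.731 with an estimated correlation). Pdgfra and Dpt had log2 changes of 0.18 and 0.14 and were not called. Of 20 extracellular matrix genes Vcan, a proteoglycan, rose from 20.1 to 30.5 RPKM, with 0 over the list alone (median 0.25, camera adjusted p = 6.64e-04, and adjusted p = 0.651 with an estimated correlation). Fn1, Thbs1 and Loxl2 had log2 changes of 0.55, 0.53 and 0.31 without a call, except Fn1 without WT replicate 3 (adjusted p = 0.0302). The fibroblast list call was lost without WT replicates 1 or 2 or Rbpms KO replicates 1 or 2 (adjusted p up to 0.250). Only the call of Emcn, of the genes named here, held without each library. The others were lost without WT replicates 1 or 2, Tie1, Cgnl1 and Postn also without Rbpms KO replicate 1, all but Npr3, Adgrg6 and Vcan without Rbpms KO replicate 2, Tmem108, Tie1, Tcf21, Postn and Vcan without Rbpms KO replicate 3, and Vcan without WT replicate 3, with adjusted p up to 0.198 for Tie1.

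Lists of epicardial, neural and red cell genes were called lower at the preset correlation. Krt8 fell from 7.81 to 3.98 RPKM, 1 of 11 epicardial genes (4 over the list alone; median -0.23, camera adjusted p = 0.0286, and adjusted p = 0.618 with an estimated correlation). Krt19, Aldh1a2 and Upk3b had log2 changes of -0.97, -0.36 and -0.35 and were not called, except Krt19 without Rbpms KO replicates 1 or 3 (adjusted p down to 0.0181) and Aldh1a2 without WT replicate 3 (0.0446). Krt8 and Krt19 are also keratins of simple epithelium, of which Cdh1 (from 5.28 to 0.716 RPKM) and Epcam (from 3.76 to 0.424 RPKM), named after their values were seen, fell too. Prph (from 1.27 to 0.234 RPKM) and Tubb3 (from 1.54 to 0.466 RPKM), of neurons, fell among 5 tested neural genes (3 over the list alone; median -0.62, camera adjusted p = 0.0302, and adjusted p = 0.518 with an estimated correlation), and Stmn2 had a log2 change of -0.62 and was called only without Rbpms KO replicate 1 (adjusted p = 0.00832). Erythroid genes had 0 of 8 called over all genes or the list alone, with a median of -0.59 (camera adjusted p = 0.0434, and adjusted p = 0.731 with an estimated correlation), and Hbb-bt, Alas2 and Bpgm had log2 changes from -0.79 to -0.40. The erythroid call was lost without WT replicate 3 or Rbpms KO replicates 1 or 2 (adjusted p up to 0.193), and the epicardial call without Rbpms KO replicate 3 (0.0693). The call of Prph held without each library, that of Krt8 was lost without WT replicate 2 or Rbpms KO replicate 2 (up to 0.0882), and that of Tubb3 without WT replicates 1 or 2 (up to 0.0993).

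The remaining cell type lists were not called. Of 12 macrophage genes Lyz2 fell from 11.9 to 8.15 RPKM (1 over the list alone; median -0.01, adjusted p = 0.852), a call lost without WT replicates 1 or 2 or Rbpms KO replicates 2 or 3 (up to 0.211) and after rescaling (0.0526). Atrial genes had 0 of 12 called (median 0.17, adjusted p = 0.103; 0.00697 without WT replicate 3, and called also without Rbpms KO replicate 3), with 406 and 626 RPKM for Nppa. Skeletal muscle genes had 0 of 8 called (median -0.15, adjusted p = 0.660), and lymphatic genes 0 of 6 (median 0.10, adjusted p = 0.403). Of the adipocyte list 3 genes were tested and 0 called, and of the thymocyte list 0 were tested. Of the list of genes with alternative exons in heart 50 were tested in RPKM, and Smtn fell from 9.90 to 7.29 RPKM (0 falls over the list alone). The call of Smtn held only without Rbpms KO replicate 2 (adjusted p up to 0.213 otherwise) and was lost after rescaling (0.0579). Cacnb2 and Pdlim5 were called without WT replicate 3 or Rbpms KO replicate 1 (adjusted p down to 0.0336 and 0.0381). Of the 5 sex genes 0 were called, but Xist was without Rbpms KO replicate 2 (adjusted p = 1.16e-04).

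Several genes beside Rbpms on chromosome 8 rose. Dctn6, a subunit of dynactin, rose (17.9 ± 2.07 RPKM in WT and 38.8 ± 8.53 RPKM in Rbpms KO; SD, n = 3), Gtf2e2, a general transcription factor subunit, from 14.4 to 23.3 RPKM, and Saraf, a regulator of calcium entry, from 26.9 to 40.1 RPKM. With Leprotl1, named after its value was seen (from 10.6 to 13.4 RPKM), 4 of 10 tested genes of the neighbour list rose and 1, Rbpms itself, fell (8 and 1 when adjusted over the list alone). The call of Dctn6 was lost without WT replicates 1 or 2 (adjusted p up to 0.0593), and those of Gtf2e2 and Saraf held without each library. Leprotl1 was not followed in those fits.

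**Figure D2:**
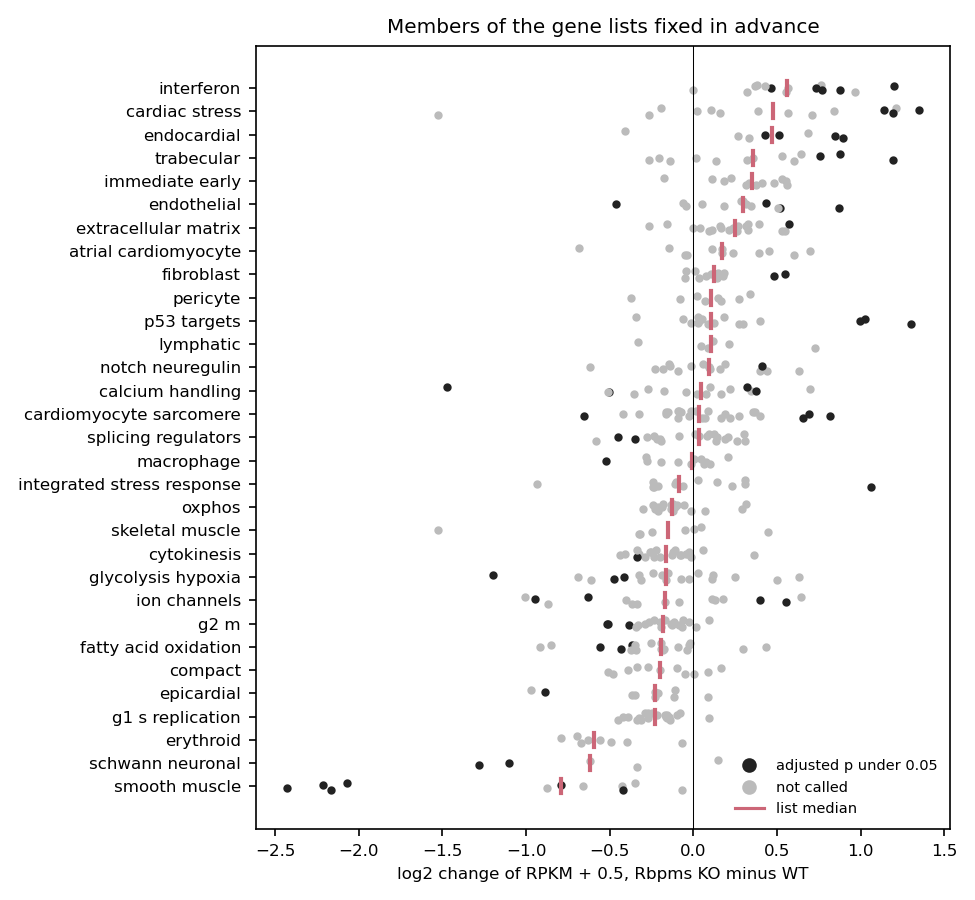
Log2 change of RPKM + 0.5 (Rbpms KO minus WT) of each tested member of the 31 gene lists compared, with black points at an adjusted p below 0.05 and a bar at the list median. The smooth muscle list lay lowest, with a median of -0.79, and the interferon list highest, with 0.56.

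As a whole, 18 of 31 lists were called by camera at the preset correlation, 9 up and 9 down. At the same setting, the 9 splits of the libraries that mixed the genotypes called 8 to 14 lists. With a correlation estimated from the data 0 were called (lowest adjusted p = 0.479), and fry called 1, smooth muscle.

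Exon use differed between the 2 sets of 3 libraries in the authors' deposited splicing table. That table does not name the sets' genotypes, so no direction by genotype is given. The libraries are of whole tissue, so a difference in the mix of cells cannot be told apart from a change within a cell type. In the authors' deposited table, 168 skipped exon events in 128 genes passed the threshold, 93 with higher inclusion in the first set and 75 in the second, and the sets did not overlap for 154. The largest difference in the authors' deposited table was in titin, Ttn, the giant spring protein of the sarcomere (chromosome 2, 76965777 to 76965914, GRCm38, a coding exon), with a mean inclusion of 80.0% in the first set and 23.0% in the second. The authors' deposited table gave 74.3% in the first set and 26.0% in the second for Mical3 (chromosome 6, 121009777 to 121009884) and 34.0% in the first set and 80.8% in the second for Clta, clathrin light chain (chromosome 4, 44031400 to 44031435). For Actn1, an actin crosslinker (chromosome 12, 80170686 to 80170766), the authors' deposited table gave 14.1% in the first set and 59.5% in the second, and for Cald1 (chromosome 6, 34747886 to 34747969) 72.5% in the first set and 29.7% in the second. Tmed2 (chromosome 5, 124543487 to 124543507), Camk2g (chromosome 14, 20747819 to 20747851), Camk2d (chromosome 3, 126805857 to 126805916) and Ppfia1 (chromosome 7, 144514872 to 144514946) were also named by the rule from the authors' deposited table, with differences of 40.5 to 41.7 percentage points. Some exons stood in more than 1 event of the authors' deposited table, and the event with the largest difference is given. The Camk2d event had a mean of 30.8 reads per library. Another event of that exon, with 158.8 reads, had 21.6% in the first set and 33.3% in the second. Another event of the Cald1 exon, with 151.5 reads, had 37.4% in the first set and 16.3% in the second. Ect2, a protein needed in cytokinesis (chromosome 3, 27148795 to 27148887, a coding exon of 93 bases), stood among them in the authors' deposited table with 85.9% in the first set and 45.1% in the second (FDR = 4.76e-08). All 10 exons were coding exons of GENCODE release 21.

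**Figure D3:**
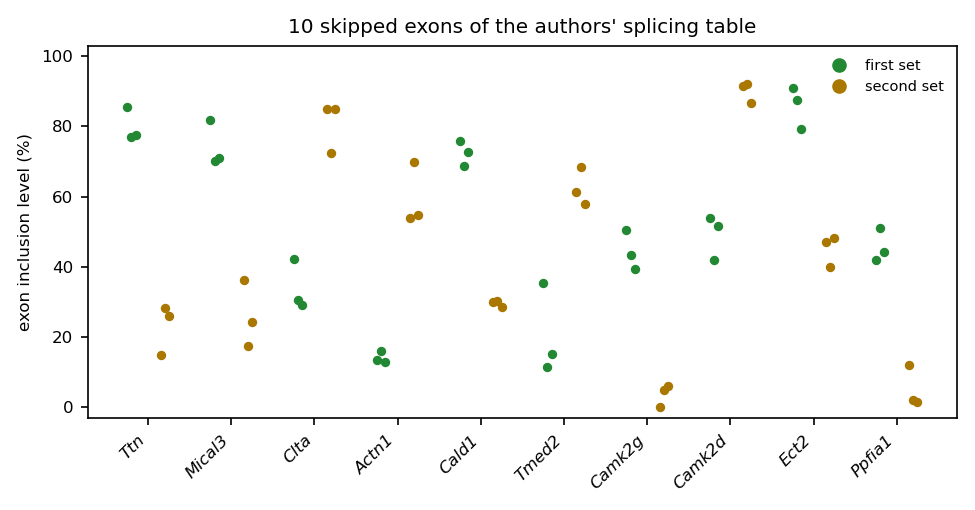
Inclusion level (percent) of the 10 skipped exons named by the rule (non-overlapping sets, 1 exon per gene, ties by the lower FDR) from the authors' deposited splicing table, for each of the 3 libraries of the first set and of the second set. The sets did not overlap for any exon shown, and the table does not say which set is which genotype. An exon in more than 1 event is shown for the event with the largest difference.

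Of the genes listed in advance for alternative exons in heart, 21 had a skipped exon past the threshold in the authors' deposited table. Besides Ttn, Actn1 and Camk2d, the authors' deposited table gave 90.4% in the first set and 50.8% in the second for Mprip (chromosome 11, 59772152 to 59772217), and 53.3% in the first set and 85.4% in the second for Ryr2, the calcium release channel (chromosome 13, 11903218 to 11903238, 21 bases). For Tnnt2, cardiac troponin T (chromosome 1, 135843785 to 135843814, 30 bases), the authors' deposited table gave 52.8% in the first set and 22.0% in the second, with the most reads of these named events, 3120 per library. Another event of the same exon in the authors' deposited table, with 4230 reads per library, had 32.2% in the first set and 9.6% in the second. The named exons of Svil, Nexn, Pdlim5, Fn1, Macf1, Nebl, Fxr1 and Pkm had higher inclusion in the first set of the authors' deposited table, by 11.5 points for Pkm to 36.4 points for Svil. The Svil event had 10, 15 and 15 reads in the second set. These directions hold for the named exons and not for every exon of a gene. Another Svil exon (5057275 to 5057439) had 54.3% in the first set and 86.9% in the second, and another Pdlim5 exon (142306284 to 142306298) 20.8% and 35.4%. The named exons of Smtn, Mbnl2, Tead1, Lmo7, Sorbs2 and Trdn had higher inclusion in the second set of the authors' deposited table, and the mean for Smtn was 71.2% in the first set and 100% in the second. Here too other exons went the other way, such as exons of Lmo7 (101915688 to 101915744, 33.1% in the first set and 17.8% in the second) and Trdn (33437718 to 33437747, 99.2% and 87.6%). Smtn was also among the genes called in RPKM.

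The other event types in the authors' deposited table were fewer, with 34 pairs of mutually exclusive exons, 5 alternative 3' splice sites, 7 alternative 5' splice sites and 2 retained introns, and 141 genes had an event of any type. The largest differences in the authors' deposited table for mutually exclusive exons were in Ttn (86.7% in the first set and 32.5% in the second) and Actn1 (24.0% in the first set and 68.6% in the second), as inclusion levels of the table. In the authors' deposited table Nptn (51.9% in the first set and 81.7% in the second) and Cacna2d1 (34.2% in the first set and 60.0% in the second) led the alternative 3' splice sites. Popdc2 (46.4% in the first set and 73.2% in the second) and Tacc2 (50.4% in the first set and 27.2% in the second) led the alternative 5' splice sites of the authors' deposited table, and Srpk3 (18.0% in the first set and 5.17% in the second) and Dmpk (16.9% in the first set and 5.17% in the second) were its retained introns.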

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

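The mean of WT replicates 1 and 2 as 1 sample, leaving out WT replicates 1 and 2 with Rbpms KO replicate 1, leaving out airway and related genes, and rescaling for the list tests were chosen after seeing the data. Among results called in the main fit or in the alternative, no named result changed direction (0 reversed). A change of sign in a result called in neither was not counted. For genes called in the main fit, groups that did not overlap fixed the direction in every fit that left out libraries. Of all comparisons, 2663 kept their side of the threshold or, for counts, stayed within 1.5-fold. Another 464 lost a call, 41 gained a call and 25 counts moved. The count of called genes, 822, ranged from 192 to 868 when 1 library was left out. It was 211 with the mean of WT replicates 1 and 2 as 1 sample, 78 without WT replicates 1 and 2 and Rbpms KO replicate 1 (a fit with 1 WT library, assumed to vary like the others), 220 at an adjusted p below 0.01, 178 at 2-fold or more and 1553 in the authors' deposited table. Fewer libraries or stricter thresholds are part of these settings, and for the authors' table the cause was not tested. The count was 796 and 818 with pseudocounts of 0.1 and 1, 979 without the filter, 605 at a mean of at least 1 RPKM, 840 after rescaling, 702 without the trend, 836 with the robust fit and 770 without airway, lung and squamous list genes. Of the 87 named genes called, Rbpms included, 29 were called in each fit that left out 1 library, 53 calls were lost without WT replicate 1 and 58 without WT replicate 2. Rescaling ended 14 of these calls and added 3.

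As a block, the replicate number gave 545 called genes, 506 of them among the 822, and 17 of 18 lists, losing oxidative phosphorylation. The numbers are not known to pair the samples. Same-numbered libraries correlated at 0.213, -0.271 and 0.122 in their deviations from the group means, and the best KO matches of WT replicates 1, 2 and 3 were replicates 1, 1 and 2. Because WT replicates 1 and 2 were so alike, these values cannot exclude a pairing. The 18 list calls became 0 with an estimated correlation and 1 with fry, which asks another question, and were 13 to 19 when 1 library was left out. Of skipped exons in the authors' deposited table, 168 became 74 at 20 percentage points or more, 320 without a coverage minimum, 122 at FDR below 0.01, 182 with at least 10 reads in every library and 190 with exon reads added. The planned limma test of exon inclusion and its alternatives were not run, because the sets carry no genotype, and the count-based tools planned only for raw counts were not run. Depth is unknown for RPKM, so no counting error is given.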

Other observations

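The tests on airway tissue, on loss of Rbpms in ventricle cells and on handling, the Fisher tests, the counts by chromosome position and the other splits for genes were chosen after the results were seen, as were the 8 lists that are named as added (airway secretory, motile cilia, cartilage, simple epithelium, alveolar, squamous and both glucocorticoid lists). Genes of ciliated cells fell with the airway secretory genes. Foxj1, the master regulator of motile cilia, fell from 3.34 to 0.0745 RPKM, Dynlrb2 from 5.63 to 0.227 RPKM and Lrrc23 from 3.44 to 0.0493 RPKM, and 19 of 21 tested cilia genes fell (median log2 change -1.63, camera adjusted p = 1.08e-25 over the 8 added lists, and adjusted p = 0.0491 with an estimated correlation). Of 14 airway secretory genes, picked partly because they had been seen to fall, 13 fell (median -4.17, camera adjusted p = 1.12e-22, and adjusted p = 0.0491 with an estimated correlation). Lists picked from these values were adjusted together with the other added lists, which can lower the adjusted p of the others. Muc5b, a mucin, fell from 5.30 to 0.0230 RPKM. Of 11 simple epithelium genes 5 fell, among them Cdh1 (from 5.28 to 0.716 RPKM) and Epcam (from 3.76 to 0.424 RPKM), with a median of -0.94 (camera adjusted p = 1.00e-08, and adjusted p = 0.153 with an estimated correlation). The alveolar list leaves out Sftpd and Sftpb, which fell, and of its 5 tested genes 0 fell and 1, Hopx, which heart muscle also expresses, rose from 194 to 298 RPKM (median 0.07, camera adjusted p = 0.0444, and adjusted p = 0.153 with an estimated correlation).

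Dusp4, among the largest rises, lies near Rbpms (chromosome 8, 34807297 to 34819894). Of 16 other tested genes within 2 Mb of Rbpms, 5 rose and 0 fell, namely Gtf2e2, Dctn6, Leprotl1, Saraf and Dusp4, or 31.3%, against 2.34% of the other tested genes (two-sided Fisher's exact p = 2.60e-05; genes near each other are not independent). Of 54 tested genes 2 to 10 Mb away 1 rose. Among 12545 overlapping windows of as many neighbouring genes elsewhere, 13 held 5 or more rises (0.104%). The labels do not describe the targeted allele, and no explanation was tested.

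The loss of airway genes was weighed against 3 sources. Airway wall in the WT dissections may have brought them, and then cilia, cartilage and simple epithelium genes should all fall; the highest of the 3 medians was -0.19, for cartilage, where 2 of 9 genes fell, 1 rose and the camera adjusted p was 0.0922, so the test left this open. A fall of the same genes within cells of the ventricle could not be told apart from it, since the libraries are of whole tissue. All WT libraries exceeded all KO libraries in the RPKM of Scgb3a2, by at least 32.4-fold. That gene was named among falls whose groups did not overlap, so this comparison could not decide. Smooth muscle of the airway could be the source of the smooth muscle falls, and the list's median of -0.79 lay between the bounds set beforehand for and against this.

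Keratins of squamous epithelium appeared in WT replicates 1 and 2 and Rbpms KO replicate 1. Krt13 measured 17.2 and 17.8 RPKM in WT replicates 1 and 2 and 42.4 in Rbpms KO replicate 1, against 0.0241 in WT replicate 3 and 0.0428 and 0.00649 in Rbpms KO replicates 2 and 3. Of 7 members not looked at before, such as Dsg3 and Calml3, 100% (7 of 7) were higher in each of these 3 libraries than in each of the others, as tissue such as oesophagus in the dissection may give. No biological explanation was tested, 0 of 11 tested genes were called between genotypes (median -0.43, camera adjusted p = 0.376), and 78 genes were called without these 3 libraries.

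Genes known to respond to glucocorticoids stood among the rises, including Fkbp5, Zbtb16, Tsc22d3 (from 19.8 to 42.1 RPKM), Klf15 (from 6.28 to 14.0 RPKM), Sesn1, Glul, Ddit4 and Cdkn1a, all 8 of which rose because the list was picked from the rises (median 1.18, camera adjusted p = 3.07e-10, and adjusted p = 0.116 with an estimated correlation). A raised glucocorticoid response is a candidate explanation, and of 21 tested responders not looked at before 3 rose (Klf9, Sgk1 and Cebpb) and 2 fell (Lcn2 and Angptl4), with a median of 0.41 (camera adjusted p = 9.50e-05, and adjusted p = 0.233 with an estimated correlation) at percentile 100 of 10000 random lists matched on expression. The random lists drew genes singly, so these percentiles leave out the correlation of genes that respond together and the spread between libraries. Rbpms KO replicate 1 as the only carrier was argued against within this limit. Without that library the percentile stayed at 100 with a median of 0.33. A difference in handling before lysis may also raise such genes, and the immediate early list, with a median of 0.35, also stood at percentile 100. Both therefore stay open.

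The other splits of the 6 libraries into 3 and 3 are too few for a share below 0.05. The genotype split called 822 genes and the highest of the 9 other splits 9, so that 1 of 10 splits gave as many. The mixed splits held the genotype difference inside each group as spread, so their low counts do not show how many genes chance would call. For lists the genotype split called 18 and the 9 other splits 8 to 14, and 1 of 10 splits gave as many. Groupings that mixed the genotypes thus also called lists at the preset correlation.

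Xist, expressed from the inactive X of females, and genes of the Y chromosome were both present in WT replicates 1 and 2, at 29.6 and 28.3 RPKM for Xist and 8.48 and 9.30 RPKM for Ddx3y. WT replicate 3 had 50.4 RPKM of Xist and Ddx3y listed at 0, and Rbpms KO replicate 2 had 52.3 and 0.0150 RPKM. Rbpms KO replicates 1 and 3 had 0.0352 and 0.0468 RPKM of Xist and 22.0 and 13.6 RPKM of Ddx3y.

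In the authors' deposited splicing table, lengths of skipped exons past the threshold were a multiple of 3 in 79.9% of 159 exons, against 55.7% of 3100 other exons with enough reads and a mean inclusion of 5 to 95% (two-sided Fisher's exact p = 6.11e-10). Of 40 genes listed for alternative exons in heart with such an exon 21 passed in the authors' deposited table, against 5.12% of other genes (adjusted p = 1.56e-15 over 7 lists, Fisher's exact test). The same test gave 6 of 11 sarcomere genes (adjusted p = 5.28e-05), 5 of 8 calcium handling genes (8.18e-05), 3 of 5 glycolysis genes (0.00339) and 1 of 7 cytokinesis genes, Ect2 (0.493), while splicing regulators had 1 of 12 (0.613) and G2 and mitosis genes 0 of 6 (1.00). Genes with more testable exons had more chances to pass, and some genes stand in several lists. Genes with such an exon in the authors' deposited table were called in RPKM in 10.9% of 128 cases, against 6.27% of 1977 other genes (Fisher's exact p = 0.0618), which did not pass. At an exon of Rbpms (chromosome 8, 33834304 to 33834454, coding) the authors' deposited table listed 561, 555 and 575 reads in the libraries of the first set and 3, 4 and 1 in those of the second.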
